A study of Pimephales promelas with 12 samples.

How the data were processed

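Gene expression was measured in whole larvae of the fathead minnow (Pimephales promelas), a small North American fish used in toxicity testing. The larvae were kept for 48 h in still water with IMX-101, an explosive formulation made to be less sensitive to shock that contains dinitroanisole, nitrotriazolone and nitroguanidine. The 12 samples fell into 3 groups of 4, namely unexposed controls, 2.0 mg/L and 61.7 mg/L, as the dose label of each sample gives them. Per the labels' protocols, each treatment had 4 beakers of 10 larvae in 200 mL, 4 larvae were taken per beaker, and only RNA with an integrity number above 8.0 was used. Each array therefore stood for 1 beaker, with 200 ng of total RNA labelled with Cy3. The text of the series and the treatment protocol of the samples list different concentrations, and 61.7 mg/L stands only in the first. The group names here follow the dose labels.

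Per the file headers, the arrays were of 1 Agilent design and 1 colour, and the authors read them with Agilent Feature Extraction 10.7.3.1. The deposited scanner files give each spot a processed signal, an intensity on a linear scale from which background was subtracted and which was detrended across the array surface, but which was not scaled between arrays. They also hold other columns, per the file headers, namely flags for spots well above background, saturated spots and outlying spots. The deposited value table holds 1 log2 value per probe and array. On probes with a mean log2 signal above 6, it closely followed the scanner values after a shift and centring of each probe on its median over the 12 arrays. The correlation was at least 0.999 and the slope 1 on every array. These measures do not depend on the constant subtracted from an array, so they do not show that it was the 75th percentile. The medians of the table's columns ran from -0.17 to 0.14. How the authors made it is not given in the sources used here.

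The design held 61053 non-control spots for 49849 probes, of which 41517 had 1 spot, 7973 had 2 and 359 had 10. Probe names were CONTIG (8524), SINGLET (26117), UF_Ppr_AF (14498) and UF_Ppr_AM (710) followed by a number. None of them (0) matched an identifier, symbol or accession in the RefSeq gene table used here, and the files pair no probe with a gene. Gene lists for blood, liver, muscle, nerve and stress responses had been fixed before the data were examined, with camera and fry as their tests. They could not be tested, and results are given by probe.

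From the scanner files, log2 of the processed signal was taken with no pseudocount, outlier-flagged spots were left out, and the spots of a probe were averaged. The 75th percentile of each array was then subtracted. A probe was kept if it was well above background on at least 3 of the 4 arrays of at least 1 group, which left 36996 probes and removed 12853. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, two-sided), with all 12 arrays in 1 fit of group means, 9 residual degrees of freedom and Benjamini-Hochberg adjustment. A probe was called at an adjusted p under 0.05. Figures were drawn with matplotlib 3.10.9.

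The named probes followed a rule fixed before the data were examined: the largest changes among called probes whose 4 arrays of one group all lay above, or all below, those of the other. The rule asked for gene names, so it was applied to probe names, and 2 rises and 2 falls are given. Where a probe was not well above background on any array of a group but was on every array of the other, the ratio is taken against a floor. It is not a strict lower bound. It sets the mean of the brighter group against, per array, the higher of the probe's own value and the lowest signal among probes well above background.

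Arrays were also placed on the response to 61.7 mg/L. For each array, probes were called without it and without the controls used as its baseline, and its log2 differences from those controls were regressed on the fitted changes. A slope of 1 means the average response of the other arrays. Because the called probes were picked for large changes, slopes of exposed arrays fall somewhat below 1. Each control was set against single other controls, and each exposed array against pairs of controls. The control slopes therefore cancel in their mean by design, and the groups were not treated alike. For slopes, the permutation p-values are only approximate. Measures of single arrays were compared by two-sided exact permutation tests, whose smallest p for 4 against 4 arrays is 0.0286. There were 21 such tests in one family, adjusted by Benjamini-Hochberg, so no adjusted value could lie below 0.0286.

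The fit was tested on simulated data with 200 of 36996 probes changed in each of 5 simulations. Independent normal noise was added to the control means. Its spread was the moderated spread of each probe from the fit, scaled by group, the wider spread at 61.7 mg/L included. Recovery with many changed probes was not simulated. For 2.0 mg/L against control it recovered 87% of 4-fold, 21.5% of 2-fold and 0% of 1.5-fold changes, with 0 unchanged probes called. For 61.7 mg/L against control it recovered 85.8%, 26.3% and 1.5%, and 12.8% of its calls were unchanged probes. The nominal share of false calls was 5%.

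The alternatives tried were other background corrections, scalings and filters, blocks for slide and replicate number, array weights, another variance model, fits of 2 groups, the authors' values, and leaving out each array. The planned normexp correction on mean signals was run on median signals, since the files used here hold no mean signal. The 12 arrays lay on 6 slides, each with a scan of its own, so slide and scan were 1 factor. The number of arrays limits the precision: the median half-width of the 95% interval of a log2 fold change was 0.53.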

Results

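The study asked how the transcriptome of fathead minnow larvae changed after 48 h in IMX-101, at a low and a high concentration. Each of the 12 arrays carried RNA from the larvae of 1 beaker, with 4 beakers each for the control, 2.0 mg/L and 61.7 mg/L. The share of probes well above background was 67.2% to 77.8% in the controls, 71.2% to 74.3% at 2.0 mg/L and 66.2% to 71.6% at 61.7 mg/L. The 75th percentile of the processed signal was 783 ± 123 (SD, n = 4) in the controls, 741 ± 37.9 at 2.0 mg/L and 590 ± 87.4 at 61.7 mg/L. At 61.7 mg/L it differed from the controls with p = 0.0857 (exact permutation test, adjusted p = 0.15 over 21 tests). No spot was saturated on any array (0 spots).

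The first comparison asked which transcripts changed at 61.7 mg/L against the unexposed larvae. Many probes were called: 4053 of 36996 (11%), of which 2226 rose and 1827 fell (limma, adjusted p under 0.05). In simulated data with 200 changed probes, 12.8% of the calls of this comparison were unchanged probes. A fit of both groups alone called 2081. Most exposed arrays also lay in other slide columns than the controls. On the processed signal, falls were more frequent among large changes. Of the 2113 called probes that changed at least 2-fold, 891 rose and 1222 fell, and of the 336 that changed at least 4-fold, 97 rose and 239 fell. These sizes depended on the treatment of background. With normexp the called probes had a slope of 0.65 on these values and rises were 80.9% of its calls. Large changes were not counted under normexp. The median size of a called change was 1.02 on the log2 scale and the smallest was 0.45. For 3732 of the called probes (92.1%) the 4 exposed arrays all lay on one side of the 4 controls, a separation that chance gives in 2.86% of probes and that 17.4% of all tested probes showed.

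Some probes crossed the detection limit. Across the array, 150 probes were well above background on all 4 controls and on none of the 61.7 mg/L arrays, and 114 of these were called. The opposite pattern held for 11 probes, of which 9 were called. These flags were set on signals not scaled between arrays. The 61.7 mg/L arrays were dimmer on average, with 69.1% of probes well above background against 73.5% in the controls. The imbalance was not separated from this difference in brightness. Calls were spread over the whole range of abundance. From the dimmest to the brightest quartile of 9249 probes each, 8.3%, 11.4%, 12.7% and 11.4% were called. Rises made up 46.7%, 57.6%, 50.5% and 63.1% of the calls in these quartiles. Among the 370 brightest probes (the top 1%), 15 were called, 10 of them up and 5 down, between a fall of -0.95 and a rise of 1.03 on the log2 scale. By kind of probe name, the share called was 10.8% for CONTIG, 10.9% for SINGLET, 11.2% for UF_Ppr_AF and 9.2% for UF_Ppr_AM (25 of 271 probes), and the differences were not tested.

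The files pair no probe with a gene, so the probes with the largest changes are given by their names. SINGLET_637 fell at 61.7 mg/L from -1.19 ± 0.15 to -5.9 ± 0.49 (SD, n = 4), in log2 units relative to the 75th percentile of each array. It was well above background on 4 controls and on 0 of the exposed arrays. On the processed signal it was 22.8-fold lower against the floor (limma, log2 fold change -4.7, SE 0.31, adjusted p = 2.88e-05). SINGLET_42286 fell from 0.57 ± 0.47 to -4.14 ± 1.36, with a log2 fold change of -4.71 (SE 0.59, limma adjusted p = 0.000659), and was well above background on 2 of the 4 exposed arrays. The sizes of these falls depended on the treatment of background: with normexp the log2 fold changes were -2.04 for SINGLET_637 and -2.89 for SINGLET_42286, both still called.

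CONTIG9899 was not well above background on any control and stood at 0.96 to 1.25 on 3 of the 4 exposed arrays, but 61.7 mg/L replicate 4 stayed at -6.04, not well above background. Its limma log2 fold change was 6.02 (SE 1.3, adjusted p = 0.0127), and 7.79 without replicate 4 (SE 0.44, adjusted p = 4.74e-05). It rests on signals not well above background, so no ratio is given. It was 3.48 with normexp and 9.36 with a control probe ratio as a covariate. With a fixed slide block, which took out replicate 4 as the only array on its slide, it was 7.61. SINGLET_46112 rose from -3.73 ± 1.64 to 0.95 ± 0.35, with a log2 fold change of 4.68 (SE 1.22, limma adjusted p = 0.0289). It varied widely without exposure, and 1 of the 2.0 mg/L arrays reached 0.64. Its log2 fold change was 2.97 with a fixed slide block, its adjusted p in limma ranged from 0.00848 to 0.203 over the alternatives, and leaving out 1 array ended the call in 6 of 12 fits. At 2.0 mg/L the limma log2 fold changes of these probes were 0.17 for SINGLET_637, -0.37 for SINGLET_42286 and 0.09 for SINGLET_46112, each with an adjusted p of 1; SINGLET_46112 was well above background on 2 of the 4 arrays at 2.0 mg/L and on 3 of the 4 controls. CONTIG9899 was well above background on 0 arrays of either group, so no change between them could be measured.

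**Figure D1:**
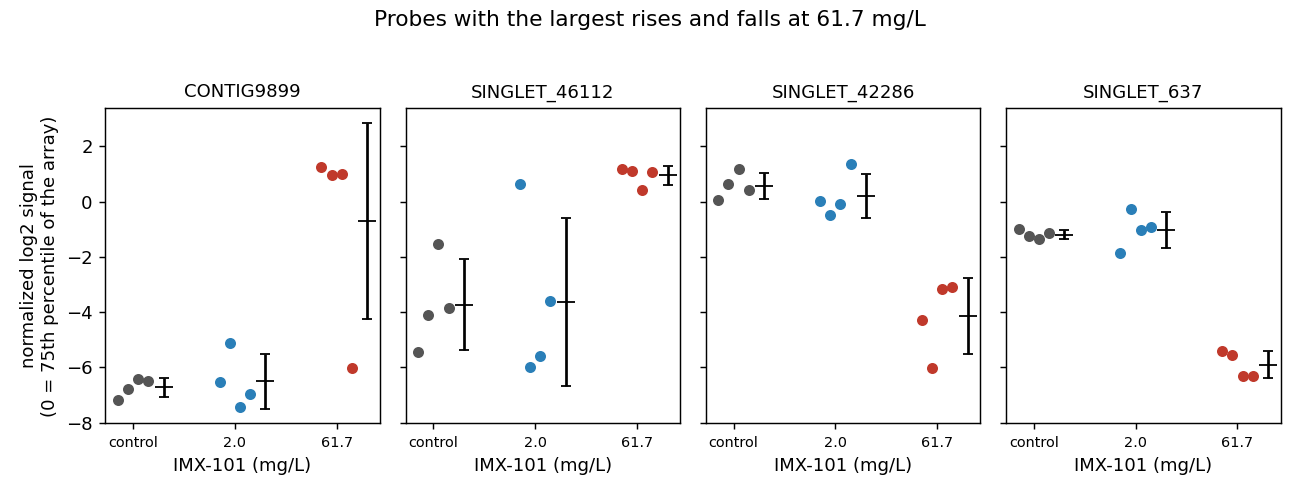
Normalized log2 signal (y axis, 0 is the 75th percentile of the array) of the named probes, by concentration in mg/L (x axis). They had the 2 largest rises and the 2 largest falls at 61.7 mg/L on the processed signal. The ranking was among called probes whose exposed arrays all lay on one side of the controls. Points are the 4 arrays of a group and bars show the mean and SD. The 61.7 mg/L arrays stand apart from the controls for each probe, except that for CONTIG9899 one of them, at -6.04, lies near the controls and like them is not well above background.

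The exposed beakers lay close together along the shared response. On probes called without the array concerned, the 61.7 mg/L arrays had response slopes of 0.82, 0.78, 0.7 and 0.76, with a mean of 0.765 ± 0.05 (SD, n = 4). The controls ranged from -0.09 to 0.09 (exact permutation p = 0.0286 against 61.7 mg/L, the smallest possible, adjusted p = 0.0751 over 21 tests). This p is approximate, since the control slopes had other baselines and cancel in their mean by design. The first principal component, with 30.5% of the variance, set the 61.7 mg/L arrays at 77.5 ± 15.4 apart from the controls at -32.8 ± 10.4 (exact permutation p = 0.0286, adjusted p = 0.0751).

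**Figure D2:**
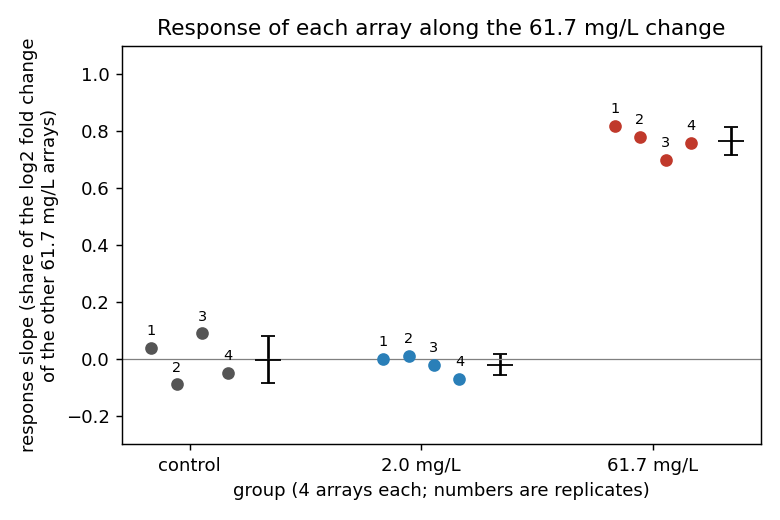
Response slope of each array (y axis, as a share of the log2 fold change fitted from the other 61.7 mg/L arrays) by group (x axis); points are arrays numbered by replicate, and bars show the mean and SD of 4 arrays. The 61.7 mg/L arrays lie between 0.7 and 0.82, while the 2.0 mg/L arrays lie between -0.07 and 0.01 and the controls between -0.09 and 0.09.

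The direction of the response depended on the treatment of background and scale. Rises were 54.9% of the calls as given, 46.9% with a median shift, 49.6% after quantile normalization and 80.9% with a normexp background correction. The number of calls depended on the controls and on how the slide was treated: leaving out control replicate 1, 2, 3 or 4 left 2659, 2187, 2670 or 2388 calls, a fit of both groups alone left 2081, and the slide as a fixed block left 281, while as a random block, with a correlation of -0.07 within slides, it left 3847, 3839 of them among the 4053. With the fixed block the log2 fold changes of the called probes had a slope of 0.97 on those without it and 100% kept their sign, while their median SE rose from 0.22 to 0.27 and the residual degrees of freedom fell from 9 to 4. Slide 2 held only 61.7 mg/L replicate 4 and slide 4 only 2.0 mg/L replicate 2, so the fixed block took both arrays out of the comparisons. Slides 3 and 5 held both groups. Probes called without slide 3 had the same sign within it in 95.3% of cases (slope 0.87, 1 exposed array against 1 control), and those called without slide 5 in 92.7% (slope 0.59, 2 exposed arrays against 1 control).

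The arrays at 61.7 mg/L were also technically less even than the others. For probes with 2 spots, the SD between the spots of one probe on the same array was 0.22, 0.37, 0.17 and 0.53 (log2) on 61.7 mg/L replicates 1 to 4, against 0.08 to 0.14 on the controls and 0.08 to 0.12 at 2.0 mg/L (61.7 mg/L against control, exact permutation p = 0.0286, adjusted p = 0.0572 over 2 tests). Brightness varied by region of the array from -0.38 to 0.41 on replicate 1, from -0.42 to 0.51 on replicate 2, from -0.02 to 0.3 on replicate 3 and from -0.72 to 0.67 on replicate 4, while on the controls no region went beyond -0.1 to 0.19. Correlations between replicate arrays were 0.937 to 0.959 at 61.7 mg/L, 0.971 to 0.983 in the controls and 0.973 to 0.985 at 2.0 mg/L (across probes, which are not independent replicates). Without 61.7 mg/L replicates 2 and 4, a fit chosen after the data were examined called 4898 probes, 2761 of them among the 4053 and none (0) in the opposite direction.

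**Figure D3:**
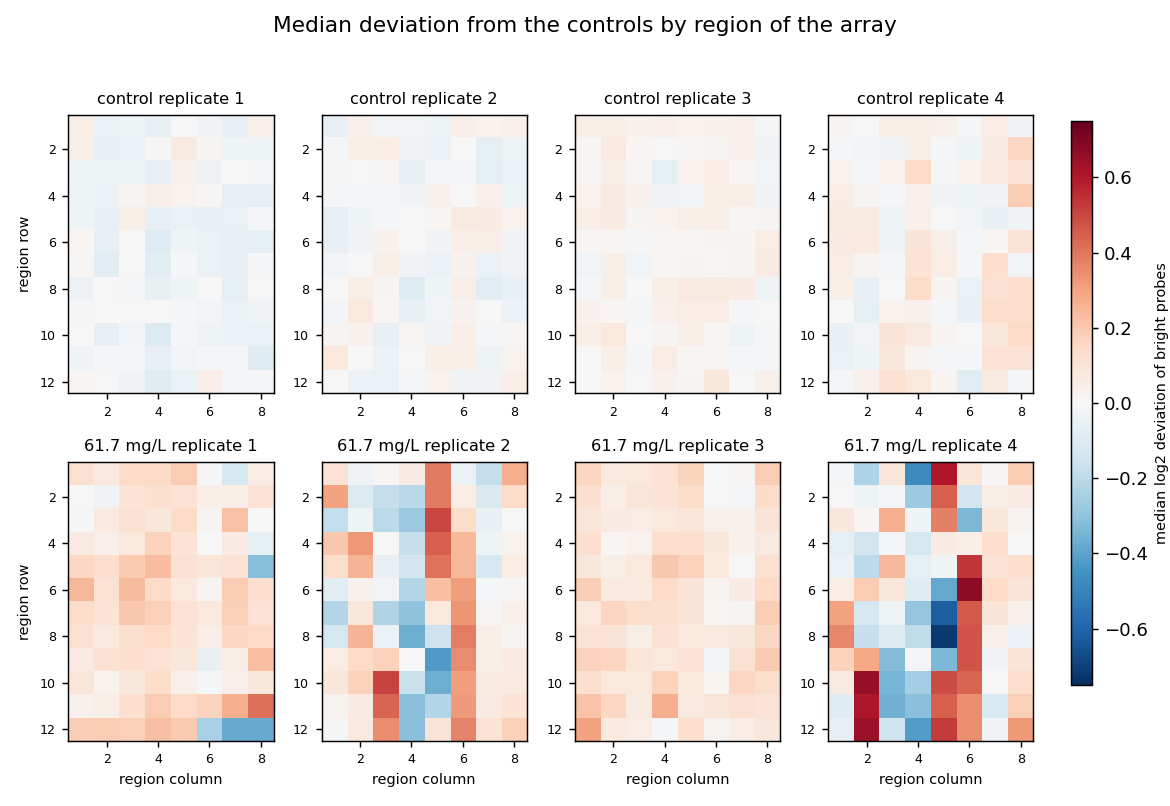
Median log2 deviation of bright probes (colour) over 12 rows and 8 columns of regions of the array surface (axes), for each control array against the other 3 controls and for each 61.7 mg/L array against the 4 controls. Raised and lowered signal reaches -0.38 and 0.41 on 61.7 mg/L replicate 1, -0.42 and 0.51 on replicate 2, -0.02 and 0.3 on replicate 3 and -0.72 and 0.67 on replicate 4, and the controls stay between -0.1 and 0.19.

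The second comparison asked whether 2.0 mg/L changed expression. No probe was called (0 of 36995, limma, smallest adjusted p = 1). At an unadjusted p under 0.05, limma gave 1375 probes (3.72%), where 1850 would be found with no effect at all, but this count depended on the fit. It was 2885 with both groups alone (smallest limma adjusted p = 0.144) and 3810 with array weights, which called 1 probe, and it ran from 646 with normexp to 3810 over the alternatives. In a test added after the data were examined, the 8 arrays were split in every way and fitted alone: 5 of 35 splits, the real one included, gave at least 2885, and the splits other than the real one gave 599 to 3504. The log2 fold change was below 1 in size for 98.7% of probes, and the change was under 1.5-fold for 94%. The response slopes at 2.0 mg/L were 0, 0.01, -0.02 and -0.07, with a mean of -0.02 ± 0.0356 (SD, n = 4). No shared movement of the probes called at 61.7 mg/L was therefore seen. The controls had -0.0025 ± 0.0822 (exact permutation p = 0.714, adjusted p = 0.789). Their mean lies near 0 by design, so this p is approximate. Detection switched in few probes, with 3 well above background on all 4 arrays at 2.0 mg/L and none of the controls, and 12 the other way round. Slides 1, 3 and 6 each held 1 array at 2.0 mg/L and 1 control, and the median log2 difference within them was -0.14, -0.05 and 0.01. Where few probes changed, the test would have missed most 2-fold changes, since 21.5% of simulated ones were recovered with 200 changed probes. Recovery of a response in many probes was not simulated.

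The third comparison set 61.7 mg/L against 2.0 mg/L. It called 5771 of 36995 probes (limma, adjusted p under 0.05), of which 3694 rose and 2077 fell at the higher concentration, and 2707 changed at least 2-fold. Of the 4053 probes called against the controls, 3314 (81.8%) were called again in the same direction and 0 in the opposite one. Independent lists of these lengths would share 325, and both lists use the same 61.7 mg/L arrays, so part of the excess may come from those shared arrays. SINGLET_637 was 25.6-fold lower than at 2.0 mg/L on the processed signal, against the floor (limma, log2 fold change -4.87, SE 0.31, adjusted p = 2.08e-05). This size rests on signals not well above background at 61.7 mg/L. CONTIG9899 was called as well (limma, log2 fold change 5.81, SE 1.3, adjusted p = 0.0118). It was well above background on 0 arrays at 2.0 mg/L and not on 61.7 mg/L replicate 4, so no ratio is given. From the dimmest to the brightest quartile, rises made up 70.5%, 68.5%, 56.9% and 60.8% of the calls. Rises were 64% of the calls, but 42.4% with a median shift, 52.1% after quantile normalization, 76.7% with a shift by spike-in controls and 82.1% with normexp. The fixed slide block left 13 calls, the random slide block 5837 (5667 of them among the 5771), the fit of both groups alone 3088, and leaving out 2.0 mg/L replicate 1 or 3 left 3439 or 3779.

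Across probes, the log2 fold changes of the 2 concentrations against the same controls correlated with r = 0.14, with 50.7% of signs shared (36588 probes, which are not independent replicates). With no effect at either concentration, the shared controls alone gave a mean r of 0.41, and from -0.1 to 0.8 over 100 simulations. The covariance was 0.026 against 0.042 in the simulations, a difference of -0.016. When the controls were split so that each concentration had its own, the mean r over 6 splits was -0.06, from -0.15 to 0.02. No correlation between the concentrations beyond that of the shared controls was detected.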

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

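The tests of array position, of spot position, of the degree of response, of power and of other splits were set before their results were seen. Those on spike-in controls, on calls at one spot, on regions, on the share of variance between spots and on splits of both groups alone were chosen after seeing the data, as was the use of the fit of both groups alone, an alternative set beforehand, as a test. Of 36 groups of 4 arrays tested for an outlying array, 6 had one beyond the 95% limit of Dixon's test, where chance gives about 1.8. Control replicate 4 stood out in 3 of them: it had 397 outlier-flagged spots (113 to 133 on the other controls), a distance of 0.593 from the rest of its group (0.424 to 0.443, log2) and an SD between spots of 0.14 (0.08 to 0.09, log2). The 75th percentile of 2.0 mg/L replicate 3 was 796.9, against 714.5 to 727.3 on the other arrays of its group. Among the named probes, CONTIG9899 was at -6.04 on 61.7 mg/L replicate 4 (0.96 to 1.25 on the others), and SINGLET_46112 was at 0.43 on 61.7 mg/L replicate 3 (1.07 to 1.19 on the others). Repeat spots, which the comparisons only average, carried a signal of their own: the SD between spots of a probe was 0.325 on average on the 61.7 mg/L arrays and 0.1 on the controls.

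The calls at 61.7 mg/L against control were weighed first. Chance is argued against but not excluded: 1 of 35 splits of the 8 arrays, the real one, gave 4053 calls and the highest other gave 2. No smaller share is possible with 35 splits. The other splits mix the groups, and any group difference widens their spread and lowers their counts. Position on the slide, which differed between the groups for 3 of the 4 exposed arrays, cannot be told apart from the dose in 3 of them; 61.7 mg/L replicate 1, whose slide column also held controls, had a response slope of 0.82, but it is 1 array. Hybridisation or labelling stays open. Of 7 E1A spike-in probes 0 reached the p of the called probes, and the largest moved by 0.17 on the log2 scale, against a median call of 1.02. However, their median SD between arrays was 0.23 at 61.7 mg/L and 0.07 in the controls, so opposite shifts may cancel in the means. Over all 21 control probes, E1A and DCP, the largest moved by 0.4. The ratio of the DCP control probes, whose meaning the files do not state, differed between the groups (-2.83 and -2.25, exact permutation p = 0.0286). With it as a covariate the called changes had a slope of 1 on those without it. Their median SE was 0.36 against 0.22, so on average precision was lost rather than size, and the fall to 447 calls tells neither way. Uneven arrays do not account for the calls as a whole, because 98% of the 752 probes called from their first spot had the same sign at their second. They may account for part of those with 1 spot. The share of rises among these ran from 25% to 89.5% over 96 regions (permutation p = 0.001, the smallest that 1000 permutations can give). After spatial correction it ran from 34.4% to 75% (permutation p = 0.6). The correction takes out regional differences of any cause by design, so this second value decides nothing. A response to IMX-101 stays open as a hypothesis for the rest.

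The wider spread among the 61.7 mg/L arrays was weighed next, with a median SD between arrays of 0.43 against 0.23 in the controls and 0.25 at 2.0 mg/L. In bright probes with 2 spots, the variance between spots of one probe was 71.7% of that between the 61.7 mg/L arrays, against 30.3% in the controls. It includes any constant difference between the 2 spots, which the variance between arrays lacks. These percentages are therefore upper estimates of a share. The SD left after subtracting it, 0.32, 0.28 and 0.28 at 61.7 mg/L, in the controls and at 2.0 mg/L, is a lower estimate. Differences between 2 arrays hold no such constant. In the bright probes they correlated between the spots with a median r of 0.32 at 61.7 mg/L and 0.76 in the controls. These values go with noise within the arrays as the main source of the spread. Over all tested probes with 2 spots, the same differences at 61.7 mg/L correlated with a median r of 0.31. That is just above the bound of 0.3 set beforehand for spot position, so that test decides nothing by itself. For beakers that responded to different degrees, the response direction took 8.2% of the deviations on average (5.5% to 13.2%), where at least 30% had been set. With a variance between spots of up to 71.7% of that between arrays in bright probes with 2 spots, 30% could hardly be reached. Replicate 3, at 13.2%, also exceeded the bound set beforehand for the opposite outcome. This test therefore decides nothing, and other differences between beakers stay open.

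The absence of calls at 2.0 mg/L was weighed last. With 0 calls in the real split, all 35 of 35 splits give at least as many (the highest other gave 1), so that count says nothing about chance; by unadjusted p under 0.05 in the fit of both groups alone, 5 of 35 splits gave at least the 2885 probes of the real one and the highest other gave 3504, so chance may account for those probes. Low power may account for it in part, since 21.5% of simulated 2-fold changes were called, while 4-fold changes were recovered in 87%. Both values hold for simulations with 200 changed probes, and power for a response in many probes was not tested. The wide spread at 61.7 mg/L in the shared estimate stays open as a cause: the fit of both groups alone also gave 0 calls, but with fewer degrees of freedom, and it gave 2885 probes at an unadjusted p under 0.05 against 1375 (limma, smallest adjusted p 0.144 against 1). No test here tells an absent response from changes of 2-fold or less in single probes, or from a few larger ones that were missed. For 61.7 mg/L against 2.0 mg/L, 1 of 35 splits, the real one, gave 5771 calls and the highest other gave 1. With the same limits, this argues against chance but does not exclude it.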

How the results depend on the processing

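Spatial correction, normexp on median signals, the spike-in shift, the covariate from control probes and the fit without 61.7 mg/L replicates 2 and 4 were chosen after seeing the data; the other alternatives were set before the data were examined. The gene list tests and the normexp correction on mean signals were not run. At 61.7 mg/L against control, 13 of 16 alternatives gave a count within 1.5 times of 4053. The exceptions were 281 calls with the slide as a fixed block, 447 with the covariate and 2081 with both groups alone. The slopes of the called probes on their main values were 0.97, 1 and 1, so on average their changes were not smaller. With both groups alone the slope is 1 by design, since the group means are the same. The median SE was larger (0.27, 0.36 and 0.24 against 0.22) and the degrees of freedom were fewer. Single probes could still lose their call to a smaller change. With the fixed slide block SINGLET_46112 went from 4.68 (SE 1.22) to 2.97 (SE 0.98). The fixed slide block also took out 61.7 mg/L replicate 4 and 2.0 mg/L replicate 2, each alone on its slide. At 2.0 mg/L, array weights called 1 probe and 15 alternatives called 0. At 61.7 mg/L against 2.0 mg/L, the fixed slide block gave 13, array weights 3731, the covariate 1489 and both groups alone 3088. No called probe of either comparison changed sign among the calls of any alternative (0 probes), but with normexp, called or not, 96.9% kept their sign against control and 98.2% against 2.0 mg/L, with slopes of 0.65 and 0.66 on their main values. The correlation of the concentrations was -0.05 with the fixed slide block and 0.39 with the covariate, and the cause was not tested. Leaving out each array gave 2187 to 4277 calls for 61.7 mg/L against control, 0 to 1 at 2.0 mg/L, 3439 to 6272 for 61.7 mg/L against 2.0 mg/L, and r from 0.1 to 0.22. Leaving out 2.0 mg/L replicate 3 or 61.7 mg/L replicate 3 gave the 1 call at 2.0 mg/L. Spatial correction gave 4530 calls, 3576 of them among the 4053. Same-numbered arrays did not deviate together (r from -0.1 to 0.1). No pairing of the beakers by number was therefore seen, but 4 numbers per comparison cannot exclude it. The replicate block gave 3292, 0 and 5030 calls in the 3 comparisons. The median log2 fold change of all probes at 61.7 mg/L against control was 0.06, and 0.2 with normexp. Against 2.0 mg/L it was 0.11, -0.04 with a median shift, 0.23 with the spike-in shift, 0.22 with normexp and 0.21 with no filter. CONTIG9899, SINGLET_42286 and SINGLET_637 were called in every alternative run on them, with log2 fold changes of 3.48 to 9.36, -5.92 to -2.89 and -4.91 to -2.04 (the smallest in size with normexp), and all 3, like SINGLET_46112, were absent from the strictest filter. SINGLET_46112 lost its call in 5 of 15 alternatives. Signal over background limits small changes in dim probes.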

Other observations

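Other values describe how the arrays differed beyond the comparisons. The second principal component, with 16.3% of the variance, placed 61.7 mg/L replicates 1 and 3 at 85.4 and 51.9 and replicates 2 and 4 at -38 and -86.7, while the 2.0 mg/L arrays lay between -9.2 and 6.8 and the controls between -9.5 and 26.4. Replicates 2 and 4 were also the 2 arrays with the largest SD between spots, and both lay in row 1 and column 1 of their slides. The log2 ratio of the control probes DCP_1_7 and DCP_1_0 was -2.83 ± 0.274 (SD, n = 4) at 61.7 mg/L and -2.25 ± 0.159 in the controls (exact permutation p = 0.0286, adjusted p = 0.0751 over 21 tests). The 75th percentile relative to the mean of the E1A spike-in controls was -3.14 at 61.7 mg/L, -3.15 in the controls and -3.25 at 2.0 mg/L (log2).

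Probes with more spots were called somewhat more often at 61.7 mg/L against control: 3225 of 30099 probes with 1 spot, 787 (11.9%) of 6619 with 2 and 41 (14.7%) of 278 with 10, with median SEs of 0.25, 0.22 and 0.19. The fold changes fitted from the first and second spots of the probes with 2 correlated with r = 0.78 across probes. Of 752 probes called at the first spot, 420 were also called at the second, where the changes had a slope of 0.88 on those at the first.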
